A study of Mus musculus with 24 samples.

How the data were processed

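Kidneys of 24 male mice with X-linked Alport syndrome, a hereditary glomerular disease caused by loss of the type IV collagen chain encoded by Col4a5, were profiled by bulk RNA sequencing at 15 weeks of age. Per the labels, 13 mice were heterozygous (HET) and 11 wild type (WT) for Nbl1, a secreted antagonist of bone morphogenetic proteins (BMPs). The libraries were made in 2 batches, with 6 HET and 6 WT mice in batch 1 and 7 HET and 5 WT mice in batch 2. Each label gives a separate mouse library. For HET replicate 8 the title and the library name give different animal numbers, and its column follows the library name. The labels do not tie replicates of one genotype to those of the other. Replicates were numbered in the order of deposition, so the numbers are names and pair nothing. The labels' protocols name 1 RNA kit, 1 mRNA library kit and a minimum RNA integrity number for all libraries.

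The authors deposited 1 table of 55487 genes that holds, for each library, expected counts, TPM and FPKM. Per the submitters' processing notes, the tools were fastp, STAR and featureCounts and the genome build was GRCm38 (mm10); versions, strand setting and annotation release are not given in the sources used here. The deposited expected counts were not whole numbers for 11.8% to 15.4% of genes in a library, as they would be if reads shared by several genes were split. How the tools named in the notes gave such values is not given in the sources used here. These expected counts were rounded to whole numbers before any test. TPM and FPKM were used as the authors deposited them, in alternatives on the log2 scale with a pseudocount of 1. Gene coordinates came from GENCODE M21 on GRCm38, in which 55141 of the 55487 identifiers were found. All per-sample columns of the table had a sample.

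The depth was 29551337 to 33019871 counts per library in batch 1 and 36380374 to 50746652 in batch 2. Genes were kept by the filterByExpr function of edgeR 4.0.16 in R 4.3.3, with its minimum count of 10, which left 18339 genes holding 99.9% of the counts. Libraries were scaled by TMM. HET was tested against WT with edgeR's quasi-likelihood test, robust dispersion estimates and batch as a covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The same test was run within each batch, for the interaction of genotype with batch, for batch 2 against batch 1, and for the slope on the log2 CPM of Nbl1 with batch and genotype as covariates. Intervals are at 95%. Standard errors of log2 fold changes were taken from the F statistic. All 61 pairs of libraries of one genotype and batch differed by more than counting noise, with a chi-square per degree of freedom of 9.61 at the lowest.

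The 37 gene lists cover BMP and TGF-beta signalling, matrix, injury, inflammation, nephron segments, metabolism, sex-biased genes, the neighbourhood of Nbl1 and tissues that a dissected kidney can carry. Lists with at least 5 tested members, 35 in number, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, and with fry. The adrenal gland list and the skeletal muscle list had fewer tested members and were not tested as lists. A list score is the mean log2 CPM of its members with a prior count of 2, and scores were compared by 100000 permutations of genotype within batch. Single genes within a batch were compared by an exact two-sided permutation test. For 11 lists the score was correlated with the log2 CPM of Nbl1 within each genotype after the batch means were removed, with permutation p-values.

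Apart from exceptions stated here or where they occur, the named genes follow a rule set before the data were examined. It takes Nbl1 and Col4a5, the 10 genes of smallest p in each direction with a mean of at least 1 CPM for HET against WT, members of each list by smallest p, members of highest mean CPM in the scored lists, and the 10 genes of smallest p in each direction for the slope on Nbl1. Genes past the threshold in the interaction were to be named too, and there were none. Where the rule allowed up to 4 members of a list, the text takes the first 2 by p and the first 1 by CPM. That number was set after the data were examined and was applied to every list in the same way. Of the members this takes, 2 are not reported here; they stay in their lists, and no other member takes their place. Htr6 belongs to the list of genes beside Nbl1, and its close description was chosen after its values were seen.

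The tests were tried on simulated counts with 200 changed genes. For HET against WT in all mice, with 18339 genes tested, 68% of the 50 genes changed 1.25-fold were recovered, 92% of those changed 1.5-fold and 100% of those changed 2-fold. In batch 1 alone the shares at 1.25-fold and 2-fold were 38% and 98%, and in batch 2 alone they were 56% and 90%. Unchanged genes made up 12 of 192 calls over all mice, 15 of 167 in batch 1 (8.98%) and 8 of 168 in batch 2. Of 100 genes given a slope of 0.5 on Nbl1, 78% were recovered. The simulated changes were in genes with a mean of at least 1 CPM, each gene was drawn on its own, and all labels were right. In the real data genes can vary together, and 3 batch 1 libraries went against their labels in Nbl1 and Htr6. These shares may therefore overstate recovery there. Alternatives were the DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter of 1 CPM in 11 libraries, no batch term, limma voom with sample weights, surrogate variables from sva 3.50.0, the first principal component for the slope, TPM and FPKM in place of counts, a threshold of 0.1, each library left out in turn, and other scores. Leaving out 3 batch 1 libraries, adding adipose and urothelium scores, leaving out each library within batch 2 or for the lists, an estimated correlation for the lists within a batch, and Spearman in place of Pearson correlation were chosen after the data were examined. Kidney function, histology and other mice were not analysed here.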

Results

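The series asked whether losing 1 copy of Nbl1 changes the kidney transcriptome of male mice with X-linked Alport syndrome. NBL1 binds BMPs and keeps them from their receptors. The 24 libraries, from 13 HET and 11 WT mice, detected 23945 to 25361 genes each. The total of expected counts was lower in batch 1, at 29551337 to 33019871 per library, than in batch 2, at 36380374 to 50746652, and each batch held both genotypes.

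Nbl1 (ENSMUSG00000041120, chromosome 4, 139082284 to 139092993 on GRCm38, minus strand, protein coding) averaged 5.32 ± 1.68 CPM (SD, n = 13) in HET kidneys and 8.42 ± 3.15 CPM (SD, n = 11) in WT kidneys. With batch in the model, the HET level was 63.0% of WT, with an interval of 49.9% to 79.7%. The log2 fold change was -0.67 with a standard error of 0.17. A permutation test of genotype within batch gave a two-sided p of 0.00167, whereas edgeR's quasi-likelihood test over all genes gave an unadjusted p of 0.000813 and an adjusted p of 0.997. In batch 2 the HET level was 50.8% of WT (n = 7 and 5, exact permutation p = 0.00379), and in batch 1 it was 78.4% of WT (n = 6 and 6, exact permutation p = 0.175). The interaction of genotype with batch had an unadjusted p of 0.0790 for Nbl1.

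In batch 1, 3 libraries, the doubted libraries, went against their labels in Nbl1 and in its neighbour Htr6. The library labelled HET replicate 6 held 299 Nbl1 counts, or 9.24 CPM, above the 3.86 to 4.89 CPM of the other 5 HET libraries of batch 1, and an Htr6 count of 0, which allows up to 3 counts. The other 5 held 8 to 39 Htr6 counts. The library labelled WT replicate 1 held 177 Nbl1 counts, or 5.41 CPM, and 26 Htr6 counts. The library labelled WT replicate 2 held 115 Nbl1 counts, or 3.62 CPM, and 14 Htr6 counts. The other 4 WT libraries of batch 1 held 7.0 to 7.78 CPM of Nbl1 and at most 1 Htr6 count. Every direction given here for HET against WT uses the groups as labelled, with these libraries in them. Without the 3 libraries, a setting chosen after the data were examined, the log2 fold change of Nbl1 was -0.91 and its adjusted p by edgeR's quasi-likelihood test was 0.000492. That value is circular for Nbl1 and Htr6, which picked out the libraries.

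Htr6 (ENSMUSG00000028747, chromosome 4, 139061108 to 139075570, minus strand), which encodes a serotonin receptor, lies 6713 bases downstream of Nbl1 on the same strand. It had at least 3 counts in 12 of 13 HET libraries and fewer than 3 in 9 of 11 WT libraries. In batch 2 it had 12 to 49 counts in the 7 HET libraries and 0 to 2 in the 5 WT libraries, 205 counts against 2 in all, and it was the only gene called there by edgeR's quasi-likelihood test (log2 fold change 5.98, standard error 0.56, adjusted p = 9.22e-05). The fitted fold depends on the prior count, because 4 of those WT libraries had no count. Without WT replicate 9, which held the 2 WT counts, the log2 fold change in batch 2 was 7.91. The exact permutation p in batch 2 was 0.00126, and in batch 1 it was 0.152. Over all mice the log2 fold change was 2.72 with a standard error of 0.68 and an adjusted p of 0.997. The mean level was low, at 0.697 ± 0.367 CPM in HET (SD, n = 13) and 0.121 ± 0.258 CPM in WT (SD, n = 11).

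**Figure D1:**
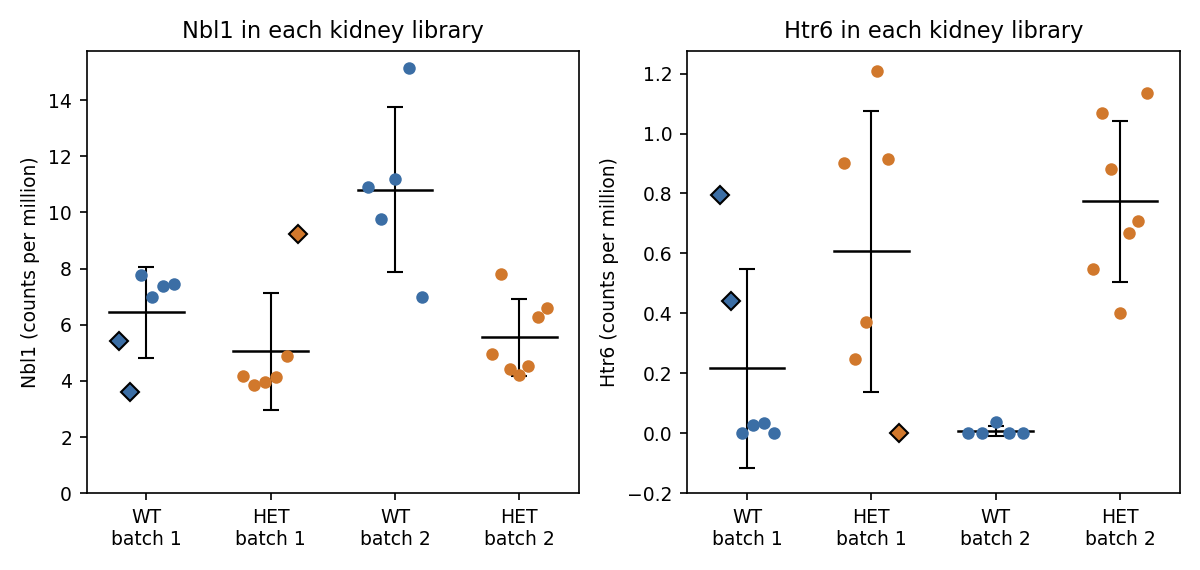
Nbl1 (left) and Htr6 (right) in CPM in each library, by genotype label and batch. Circles and diamonds are single mice, lines are group means and bars are SD; diamonds mark the 3 batch 1 libraries that went against their labels, and in batch 2 all 7 HET libraries had more Htr6 than the 5 WT libraries.

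Col4a5 (ENSMUSG00000031274, chromosome X, 141475385 to 141689234, plus strand), the gene behind the disease model, was present in every library at 23.2 ± 2.87 CPM in HET (SD, n = 13) and 24.8 ± 2.00 CPM in WT (SD, n = 11). Its log2 fold change was -0.09 with a standard error of 0.05 and a permutation p of 0.130. The exact permutation p was 0.786 in batch 1 and 0.122 in batch 2. In batch 2 the HET level was 88.4% of WT, with an interval of 79.0% to 99.0%. There edgeR's quasi-likelihood test gave an unadjusted p of 0.0472 and an adjusted p of 0.595.

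No gene of the 18339 tested passed the threshold between HET and WT kidneys over all mice. The edgeR quasi-likelihood test gave 0 genes, with a smallest adjusted p of 0.997, and the DESeq2 Wald test and limma voom also gave 0. Without the 3 doubted libraries edgeR gave 2 genes, Htr6 and Nbl1. At an unadjusted p under 0.05 there were 755 genes, 4.12% of those tested, 455 higher and 300 lower in HET. The genes of smallest p on the higher side included Mterf1b at a log2 fold change of 0.45, Gm19721 at 0.47, Gm27029 at 0.69, Gm43658 at 0.57, A330023F24Rik at 0.17, Gm49616 at 0.45, Sgpp2, which makes sphingosine from its phosphate, at 0.14, the unconventional myosin Myo5c at 0.15, the kinase Srpk2 at 0.10 and the mitochondrial ribosomal protein Mrps6 at 0.15. Those on the lower side were, beside Nbl1, the pseudogenes Gm12895 and Gm12896 at -0.68 each, Supt20 at -0.11, the minor spliceosome RNA Rnu12 at -0.54, Fcamr at -0.29, 1 of the Rnu3a copies, a U3 small nucleolar RNA (ENSMUSG00000065870), at -0.73, Ankra2 at -0.16, Mid1-ps1 at -1.93 and the riboflavin transporter Slc52a3 at -0.13. None of these 20 genes passed. Gm12895 and Gm12896 had identical counts in each library, so their reads cannot be separated, and their log2 fold change in batch 2 against batch 1 was -9.54. On the TPM scale their sign turned, to 0.046. For Rnu12 and the Rnu3a copy the batch log2 fold changes were -11.60 and -10.02, so the values of these 4 genes rest on batch 1, which holds the doubted libraries.

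**Figure D2:**
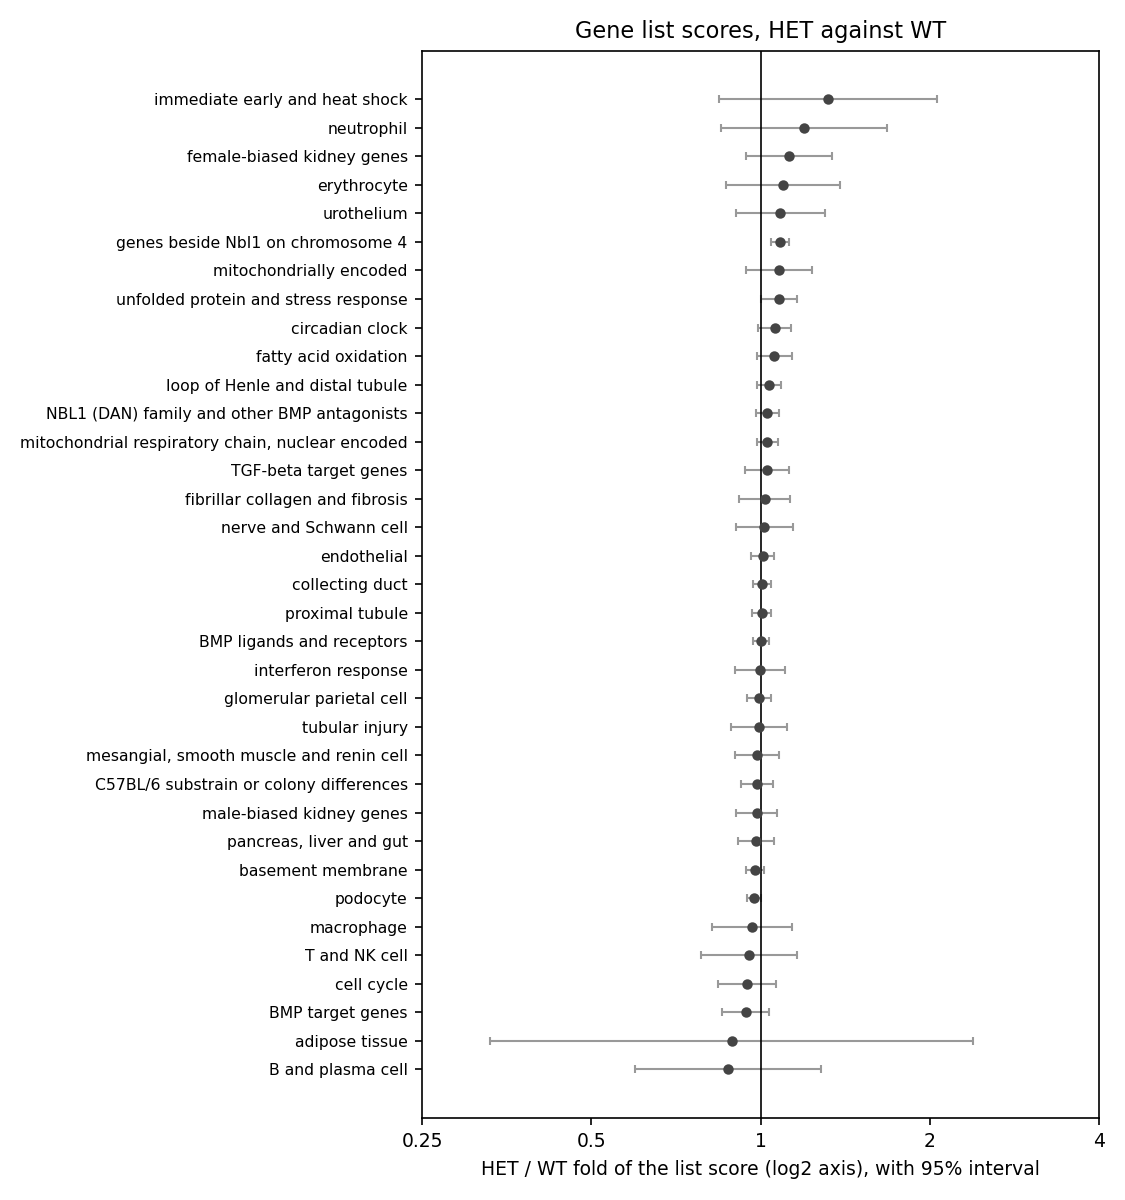
Fold of each list score in HET against WT kidneys, on a log2 axis, for the 35 lists tested; points are the batch-adjusted folds and bars the 95% intervals. The fibrosis list sits at 1.02 and the tubular injury list at 0.994, and the adipose list has the widest interval, from 0.330 to 2.39.

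The markers of kidney damage lay close to 1. The fibrillar collagen and fibrosis score was 1.02-fold in HET, with an interval of 0.916 to 1.13, and 0 of its 32 tested members passed. The score difference on the log2 scale was 0.09 in batch 1 and -0.05 in batch 2. Camera at its preset correlation called the list higher in batch 1 alone (adjusted p = 0.00428, or 0.899 with an estimated correlation), and leaving out 1 library of batch 1 ended that call for 5 of the 12: HET replicate 1 (adjusted p = 0.329), HET replicate 3 (0.0769), the library labelled WT replicate 2 (0.159), WT replicate 3 (0.117) and WT replicate 6 (0.0832). Without the 3 doubted libraries the call in batch 1 alone held (camera adjusted p = 0.0444 at the preset correlation). Over all mice without them the list was not called (0.972, direction lower). In batch 2 alone the direction was lower and not called (0.0787). Collagen I, from Col1a1, had a log2 fold change of 0.00056 with a standard error of 0.12, and its sign turned in several alternatives. Among the myofibroblast genes Tagln stood at 0.17 and Acta2 at 0.15, and the matrix proteoglycan gene Bgn at 0.02. The tubular injury score was 0.994-fold (0.885 to 1.12), with Cdkn1a at 0.18, Plaur at 0.13 and osteopontin, from Spp1, at 0.01 with a standard error of 0.14. The TGF-beta target score was 1.03-fold (0.937 to 1.12), with Tgfb3 at 0.25 and Snai2 at -0.26. None of these members passed the edgeR test.

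The BMP pathway, on which NBL1 acts, gave scores of 1.03-fold (0.982 to 1.08) for the NBL1 family and other BMP antagonists, 1.00-fold (0.968 to 1.03) for BMP ligands and receptors, and 0.941-fold (0.854 to 1.04) for BMP target genes. Of the 12 BMP targets tested, 1 had a positive log2 fold change and 11 did not, and 0 passed. Hey1 stood at -0.36, Bambi at -0.14, and Id2, the most abundant target, at -0.0033 with a standard error of 0.06. Camera called the BMP target list lower (adjusted p = 0.0358), which it was not with an estimated correlation (adjusted p = 0.941). The antagonists Kcp and Dand5 stood at -0.15 and 0.17, Smad9 at -0.19 and the receptor gene Bmpr1b at 0.09.

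Camera at its preset correlation called 8 of the 35 lists, and 0 with an estimated correlation, where every adjusted p was 0.941. The lists called lower were podocyte (adjusted p = 0.00409), cell cycle (0.00831), basement membrane (0.0357) and BMP targets, and those called higher were the nuclear-encoded respiratory chain (0.00169), immediate early and heat shock (0.00169), unfolded protein and stress response (0.00727) and loop of Henle and distal tubule (0.0304). Fry called 0 lists, with a smallest adjusted p of 0.941, and 0 for change in either direction, at 0.802. The podocyte score was 0.973-fold (0.945 to 1.00), with Cdkn1c at -0.13 and the collagen IV chain gene Col4a3 at -0.09. The basement membrane score was 0.978-fold (0.942 to 1.02), with Lama1 at -0.09. Cell cycle was 0.946-fold (0.841 to 1.06), with Birc5 at -0.24 and Plk1 at -0.23. Immediate early and heat shock was 1.32-fold (0.842 to 2.06), and all 18 members had positive log2 fold changes, with Fosb at 2.04 and Egr3 at 1.26. Single libraries carried part of this: without HET replicate 5 the list score was 1.16-fold, its camera call ended (adjusted p = 0.0911) and Egr3 stood at 0.61, and without HET replicate 12 Fosb stood at 1.31. Unfolded protein and stress response was 1.08-fold (1.00 to 1.16), with Atf3 at 0.84 (0.39 without HET replicate 5) and Herpud1 at 0.21. The nuclear-encoded respiratory chain was 1.03-fold (0.984 to 1.07), with Cox4i1 and Ndufb5 both at 0.07, and loop of Henle was 1.04-fold (0.986 to 1.09), with uromodulin, from Umod, at 0.11 and Tmem72 at 0.08. On the log2 scale, the score differences in batch 1 and batch 2 were -0.03 and -0.05 for podocyte, -0.01 and -0.15 for cell cycle, 0.03 and -0.09 for basement membrane, -0.0066 and -0.17 for BMP targets, -0.02 and 0.10 for the respiratory chain, 0.39 and 0.41 for immediate early, -0.00485 and 0.23 for unfolded protein, and -0.02 and 0.13 for loop of Henle. With 1 library left out in turn, the preset-correlation calls of the podocyte, respiratory chain and unfolded protein lists held in all 24 fits, and that of immediate early in 23. Those of cell cycle held in 19 (largest adjusted p 0.142, without HET replicate 2), of basement membrane in 18 (0.356, without WT replicate 8), of loop of Henle in 16 (0.285, without WT replicate 10) and of BMP targets in 13 (0.173, without HET replicate 9). Without the 3 doubted libraries camera called 11 lists, and none with an estimated correlation (smallest adjusted p 0.671).

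For the 35 list scores, permutation of genotype within batch called 1 list after adjustment, the genes beside Nbl1 (1.08-fold, 1.04 to 1.12, p = 0.00049, adjusted p = 0.0171). Without Htr6 its fold was 1.00. Htr6 was the only one of its 23 members, and of the members of all lists, to pass when adjusted over the list alone, and 0 members of any list passed over all genes. Ddost, another neighbour, stood at 0.06. The unfolded protein list had p = 0.0394 and an adjusted p of 0.674.

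The remaining lists had intervals that include 1, and none was called over all mice. In batch 2 alone, camera at its preset correlation called 14 lists, the 8 above and 6 of the remaining ones: adipose (adjusted p = 0.00213) and mesangial, smooth muscle and renin cell (0.00240) lower, and mitochondrially encoded (0.00176), neutrophil (0.0331), erythrocyte (0.0331) and fatty acid oxidation (0.0342) higher. With an estimated correlation 0 lists were called there, and the smallest adjusted p of any list was 0.588. The score differences in batch 1 and batch 2, on the log2 scale, were 0.39 and -0.75 for adipose, 0.05 and -0.09 for mesangial, -0.05 and 0.28 for mitochondrially encoded, 0.07 and 0.46 for neutrophil, -0.11 and 0.38 for erythrocyte, and 0.05 and 0.12 for fatty acid oxidation. Among immune cells the scores were 0.965-fold (0.818 to 1.14) for macrophage, with Gpnmb at -0.45 (0.08 without WT replicate 10), Trem2 at -0.20 and Cd74 at -0.02; 0.955 (0.784 to 1.16) for T and NK cell, with Icos at -0.47, Cd3d at -0.41 and Thy1 at -0.05; 0.876 (0.598 to 1.28) for B and plasma cell, with Mzb1 at -0.40 and Igkc at -1.0 (-1.66 without HET replicate 13 and -0.28 without the library labelled WT replicate 1); 1.2 (0.852 to 1.68) for neutrophil, with S100a8 at 1.02 and S100a9 at 0.82 (0.59 and 0.42 without HET replicate 5); and 0.997 (0.901 to 1.10) for the interferon response, with Cxcl9 at -0.27 and Oas2 at -0.12. Glomerular parietal cell was 0.995 (0.947 to 1.05), with Pax8 at 0.09 and Akap12 at 0.12. The mesangial, smooth muscle and renin cell score was 0.987 (0.901 to 1.08), with Tbx18 at -0.45 and Pdgfrb at -0.03, and endothelial was 1.01 (0.963 to 1.06), with Esam at 0.10, Egfl7 at 0.08 and Eng at -0.02. Proximal tubule was 1.00 (0.966 to 1.04), with the organic anion transporter gene Slc22a6 at -0.08, Slc5a1 at 0.09 and Lrp2 at 0.02, and collecting duct was 1.01 (0.969 to 1.05), with Aqp2 at 0.24 and Slc4a1 at -0.08.

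In metabolism, fatty acid oxidation was 1.06-fold (0.985 to 1.14), with Pdk4 at 0.50 and Cyp4a10 at 0.24, and the mitochondrially encoded list was 1.08 (0.943 to 1.24), with mt-Nd6 at 0.34 and mt-Co2 at 0.35. Circadian clock was 1.06 (0.988 to 1.13), with Bhlhe41 at 0.30 and Cry1 at 0.25. Male-biased kidney genes were 0.984 (0.905 to 1.07), with Cyp4b1 at -0.14 and Slco1a1 at -0.25, and female-biased genes 1.12 (0.943 to 1.34), with Slc47a1 at -0.06 and Slc22a29 at 0.25. Substrain or colony genes were 0.986 (0.922 to 1.05), with Crb1 at -0.31 and Cyfip2 at 0.07. Of other tissues, adipose was 0.889 (0.330 to 2.39), with Lipe at -0.15 and Plin1 at -0.48; erythrocyte 1.10 (0.868 to 1.38), with Bpgm at 0.05; pancreas, liver and gut 0.982 (0.911 to 1.06), with Ttr at -0.30 and Cela1 at 0.07; urothelium 1.09 (0.906 to 1.30), with Krt15 at 0.43 and Upk1a at 0.14; and nerve and Schwann cell 1.02 (0.902 to 1.14), with Nefm at 0.15. Some lists had a median and a mean of opposite sign, both near 0: BMP ligands and receptors, interferon response, proximal tubule, and pancreas, liver and gut. For the TGF-beta targets and the collecting duct the median and mean lay above 0 and camera's direction was down. Akr1b7 and Star, from the adrenal list, stood at 0.11 and 0.05, and Mylpf and Pvalb, from the skeletal muscle list, at 0.19 and 0.0084. Beside Gpnmb and Col1a1, single left-out libraries turned the sign of Id2, Bgn, Spp1, Cd74, Thy1, Pdgfrb, Star and Pvalb, all near 0.

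Within batch 1 edgeR's quasi-likelihood test called 0 genes (smallest adjusted p 0.166, 509 genes at an unadjusted p under 0.05), and within batch 2 it called Htr6 alone (1530 at an unadjusted p under 0.05). The DESeq2 Wald test called 1 gene in batch 1, Slitrk6, and 26 in batch 2, among them Nbl1, which was at -0.98 on the log2 scale, and Dynlt1b, Gpr137b-ps and Selenos. Htr6 was not among the 26: its log2 fold change there was 6.35 with an unadjusted p of 3.79e-11, and DESeq2's filter on mean counts gave it no adjusted p. These 4 names were chosen after their values were seen. The interaction of genotype with batch was called for 0 genes by edgeR, with a smallest adjusted p of 0.377 and 1504 genes at an unadjusted p under 0.05, and for 0 by DESeq2 (1573 at an unadjusted p under 0.05), and for 0 genes by edgeR without the 3 doubted libraries. No gene was shown to differ in its response between the batches. Without those libraries batch 1 gave 2 genes, Htr6 and Nbl1.

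Across mice, with genotype and batch in the model, no gene followed the level of Nbl1 at the threshold. Vwf, the endothelial von Willebrand factor, came closest, with a slope of 0.44 log2 units per log2 unit of Nbl1, a standard error of 0.08 and an adjusted p of 0.0777. The DESeq2 Wald test called 21 genes, Vwf among them. Without the 3 doubted libraries edgeR called Vwf alone, at a slope of 0.73 and an adjusted p of 0.0108. At an unadjusted p under 0.05 there were 2061 of 18338 genes by edgeR, 880 with a positive and 1181 with a negative slope. Other positive slopes of small p were those of Uba7 (0.37), Scarf2 (0.41), Apcdd1 (0.60), Kif21b (0.48), Tifab (0.63), Trim68 (0.38), Nav1 (0.23), the actin crosslinker Flna (0.25) and Cd34 (0.17), a marker of endothelial and progenitor cells. Negative slopes were those of Egf (-0.22), made in the distal tubule, the glycerol kinase gene Gk (-0.21), Aadat (-0.30), Sms (-0.25), Cyp2j11 (-0.21), Ccdc90b (-0.21), Cdc123 (-0.13), Itgb8 (-0.20), 4632428C04Rik (-0.71) and Gm22988 (-0.63). None of these 19 passed the edgeR test.

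**Figure D3:**
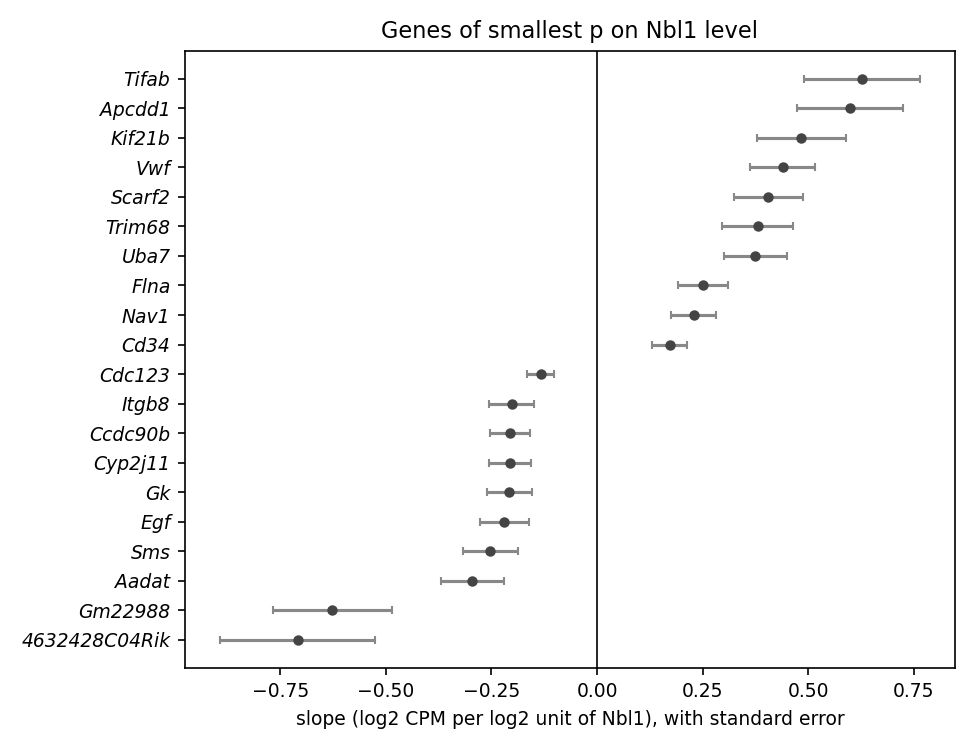
Slope of each gene on Nbl1 level, in log2 CPM per log2 unit of Nbl1, for the 10 genes of smallest p in each direction over 24 libraries; points are slopes and bars standard errors. Tifab has the highest slope, 0.63, and 4632428C04Rik the lowest, -0.71, and none of the genes passed the threshold.

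Camera at its preset correlation called 20 of the 35 lists on Nbl1 level, 14 with positive and 6 with negative slopes, and 0 with an estimated correlation, where the smallest adjusted p was 0.254. The fibrillar collagen and fibrosis list had a positive slope on Nbl1, with a median over members of 0.19 (adjusted p = 5.55e-12, or 0.266 with an estimated correlation), and 15 of its 32 members had positive slopes at an unadjusted p under 0.05. The macrophage list had a median slope of 0.25 (3.84e-09, or 0.285 with an estimated correlation), cell cycle 0.21 (1.39e-07, or 0.254) and mesangial, smooth muscle and renin cell also 0.21 (3.26e-06, or 0.254). Negative slopes were found for the mitochondrially encoded list (median -0.25, 3.73e-06, or 0.285) and for loop of Henle and distal tubule (median -0.10, 5.24e-05, or 0.254). The adipose and urothelium lists, which mark tissue around the kidney and its pelvis, had positive slopes as well, with medians of 1.07 (4.94e-07, or 0.285 with an estimated correlation) and 0.40 (6.03e-05, or 0.254). At an unadjusted p under 0.05 by edgeR's test, 0 of 13 adipose members and 3 of 8 urothelium members had positive slopes. With both scores as covariates, a setting chosen after the data were examined, the adjusted p of Vwf was 0.246 and its slope 0.37. With the first principal component of the other tested genes in the model, its adjusted p was 0.682 and its slope 0.39, camera called 13 lists, and the genes at an unadjusted p under 0.05 were 847.

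Within a genotype, Nbl1 level was set against 11 list scores in 22 relations. By Pearson correlation 0 relations passed adjustment. The closest were the endothelial score in HET (r = 0.765, permutation p = 0.00639, adjusted p = 0.141; rho = 0.890, adjusted p = 0.00924) and the mesangial score in HET (r = 0.629, permutation p = 0.0143, adjusted p = 0.158; rho = 0.808, adjusted p = 0.00968), over 13 mice. Without the 2 libraries farthest from the median of Nbl1, r was 0.723 and 0.558, and the Spearman calls ended (rho = 0.745 and 0.600, adjusted p = 0.215 each). They ended too without the 3 doubted libraries (rho = 0.720, adjusted p = 0.144, and rho = 0.657, adjusted p = 0.110). In the 11 WT mice the endothelial relation had r = 0.152 and rho = 0.0545, and the mesangial one r = 0.356 and rho = 0.155. Within the batches the endothelial r in HET was 0.802 in batch 1 and 0.745 in batch 2, and the mesangial r 0.611 and 0.668. The batch 1 values rest on 6 mice and include the library labelled HET replicate 6, whose Nbl1 stood far above the others. Without the 3 doubted libraries r over 12 HET mice was 0.697 and 0.640. In WT mice of batch 1 the endothelial and mesangial r were 0.0458 and -0.0133. No value was computed for the 5 WT mice of batch 2, since 6 was the lowest number of mice for a correlation. The fibrosis score had r = 0.473 in WT and 0.445 in HET (0.262 and 0.510 without the 2 farthest libraries), and the BMP target score 0.219 and 0.174 (-0.0154 and 0.368). Within the batches the fibrosis r was 0.0753 in WT mice of batch 1, 0.241 in HET mice of batch 1 and 0.741 in HET mice of batch 2, and the BMP target r 0.264, -0.0239 and 0.379. Batch means were removed before each correlation.

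The batches differed in most genes. Batch 2 against batch 1 gave 11645 genes by edgeR's quasi-likelihood test at the adjusted threshold, 5977 higher and 5668 lower. The RNAs of the signal recognition particle, Rn7s1 and Rn7s2, averaged 25898 CPM each in batch 1 and 9.29 in batch 2, the RNase P RNA Rpph1 2608 and 0.768, and Rn7sk, which regulates transcription elongation, 10150 and 51.9. Rn7s1 and Rn7s2 had identical values and share reads. CT010467.1 took 4.94% to 18.0% of the counts in batch 2 libraries and 0.00125% to 0.198% in batch 1, and Lars2 averaged 4552 and 85.6 CPM. Within batch 2 the share of CT010467.1 was 7.17% to 18.0% in HET libraries and 4.94% to 11.6% in WT libraries. These ranges overlap, but the HET range lies higher. What this does to the HET against WT calls in batch 2 alone was not tested. The labels name 1 mRNA library kit for both batches. Camera called 8 lists between batches at the preset correlation, each higher in batch 2, and 0 with an estimated one (smallest adjusted p 0.807). Of their members, 14 of 17 rose in the endothelial list, 19 of 21 in the interferon response, 21 of 24 in macrophage, 19 of 30 in fatty acid oxidation, 21 of 32 in fibrosis, 14 of 19 in unfolded protein and stress response, 11 of 15 in mesangial, smooth muscle and renin cell, and 7 of 7 in erythrocyte.

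**Figure D4:**
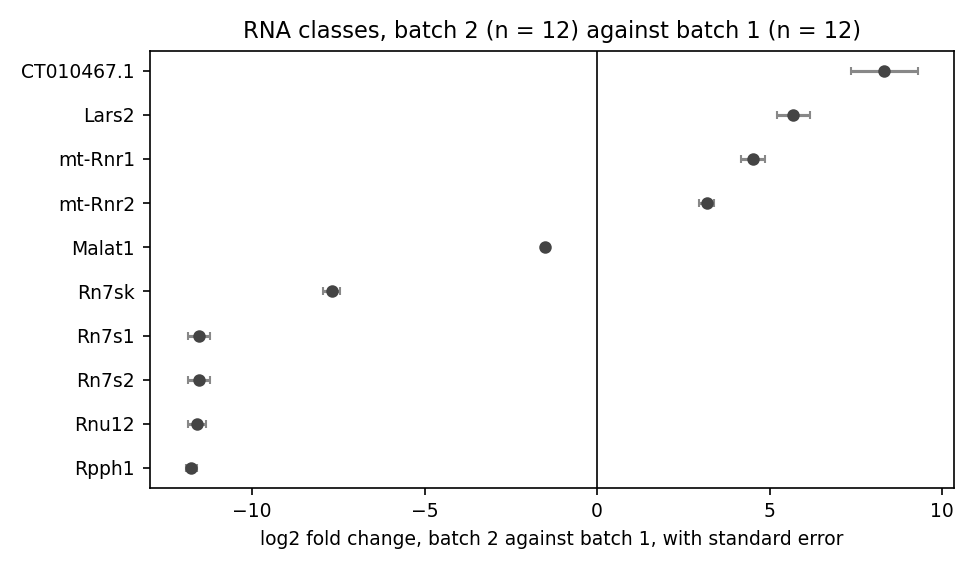
Log2 fold change of 10 RNAs in batch 2 against batch 1, with 12 libraries in each; points are fitted values and bars standard errors. Rpph1 lies lowest, at -11.76, and CT010467.1 highest, at 8.33.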

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

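The tests of counting noise and of wrong labels for the 3 batch 1 libraries, and of transcripts that run on from Nbl1 into Htr6, were chosen after the results were seen. The other tests in this part were set before their results.

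In 60 tests over 15 measures, 5 values from 4 libraries stood apart from the rest of their genotype and batch, and chance picks out about 1 in 20 such groups. The log2 CPM of Nbl1 in the library labelled HET replicate 6 was 3.22, above 1.97 to 2.31 in the others. The log2 CPM of Htr6 in WT replicate 9 was -3.42, where the other 4 WT libraries of batch 2 had no count and stood at -4.18. WT replicate 9 held 2 counts. Because the other 4 were tied, any count there would have stood apart, so this value says little. CT010467.1 took 0.198% of the counts in WT replicate 5, above 0.00125% to 0.0744% in the others. The podocyte score of WT replicate 9 was 5.52, below 5.61 to 5.64, and the TGF-beta target score of HET replicate 10 was 3.74, below 3.97 to 4.08.

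The libraries labelled HET replicate 6, WT replicate 1 and WT replicate 2 went against their labels in Nbl1 and in Htr6. Counting noise was excluded, since the largest of the 3 Poisson probabilities of their Htr6 counts was 1.29e-10, a value that leaves out the variation between mice. Nbl1 and Htr6 placed 12 of the 12 batch 1 libraries alike, with 1 HET and 2 WT libraries out of place, but the libraries were picked by these same genes, so this does not test the labels. In batch 2, where no library was doubted, Htr6 had 12 to 49 counts in HET libraries and 0 to 2 in WT libraries. By that separation each of the 3 libraries would lie with the other genotype, as wrong labels would give. Wrong labels and a biological difference in these mice still cannot be told apart, because the genotypes themselves were not analysed here, and both stay open. The libraries labelled HET replicate 6 and WT replicate 1 carry consecutive animal numbers in the labels. The column of the library labelled HET replicate 6 has a letter where the other columns of batch 1 have an animal number, and only the sample's own description ties it to its label.

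Htr6 had at least 3 counts in 12 of 13 HET libraries and in 2 of 11 WT libraries, both among the doubted ones, and 3 other WT libraries had 1 or 2 counts. Reads shared with another gene were excluded if the authors' counting splits such reads into parts, since 0% of its nonzero expected counts were not whole; whether it does is not given in the sources used here. A broad raised region was excluded, since 1 of 23 other tested genes within 1 Mb of Nbl1, or 4.35%, was higher in HET at an unadjusted p under 0.05. The nearest tested neighbours, Micos10 and Tmco4, stood at log2 fold changes of 0.03 and 0.0054. A raised stretch that reaches no further than Htr6 and Nbl1 would give the same share, so the test cannot exclude it. Transcripts that run on from Nbl1 cannot be told apart from transcripts that start at Htr6, because reads between the genes are needed. The only gene annotated between them, Gm45533, had 0 counts but lies on the other strand. An effect of the altered Nbl1 allele on its neighbour may underlie the counts. A response of Htr6 to less NBL1 was not tested directly. In batch 2, HET replicate 8 held 7.82 CPM of Nbl1 and 41 Htr6 counts. WT replicate 11 held less Nbl1, 6.999 CPM, and 0 Htr6 counts. Among the HET libraries there, replicates 8 and 13 were highest in both genes and replicate 10 lowest in both. Replicates 9 and 12 strayed from that order. These values argue against a response graded by Nbl1 RNA level in batch 2. Any other response to less NBL1 stays open.

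The batches differed in classes of RNA that lack a poly(A) tail. Of 51 tested replication-dependent histone genes, whose transcripts lack the tail, 96.1% (49) were lower in batch 2 and 1 was higher, with a median log2 fold change of -5.88. A library type that kept such RNA in batch 1 would give this. Other RNAs went the other way. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were higher in batch 2, at log2 fold changes of 4.52 and 3.18. So were Lars2 at 5.69 and CT010467.1 at 8.33, and why was not tested. Greater depth in batch 2 as the cause of the count was excluded, since 11534 genes passed with batch 2 thinned to the batch 1 median, and so was a few genes taking many counts, since 11630 passed without 14 of the most abundant genes. Batch holds other differences between cohorts, which stay open. No biological explanation was tested, because batch is not one of the study's groups.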

How the results depend on the processing

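Leaving out the 3 doubted libraries, each batch 2 library, or each library for the lists, and using Spearman correlation, were alternatives chosen after the data were examined. Over all mice, HET against WT gave 0 genes in each alternative except without the 3 libraries, where it gave 2, Htr6 and Nbl1 (log2 fold change -0.91), which picked those libraries out. With 1 library left out in turn, Nbl1 ranged from -0.81 (without the library labelled HET replicate 6) to -0.58 (without WT replicate 10). Batch 1 gave 1 gene by DESeq2 and 1 with no filter, Slitrk6 in both, and 2 without the 3 libraries. Batch 2 gave 26 by DESeq2, without Htr6, which its filter on mean counts left with no adjusted p, 3 with no filter and 0 with the 1 CPM filter, which leaves out Htr6 as well. With 1 batch 2 library left out it gave 1 to 3, Htr6 among them each time: 2 without HET replicate 7 or 8 (Dynlt1b added), 3 without HET replicate 10 (Dynlt1b and Selenos added) and 2 without WT replicate 9 (Gpr137b-ps added). The slope on Nbl1 gave 21 genes by DESeq2, 8 with no filter, 9 in WT mice alone (3 distinct, since 7 small RNA genes, Rnu1a1 among them, had identical values), 1 without the 3 libraries and 0 to 1 with 1 library left out: 1 without the library labelled HET replicate 6 (Gm22513) and 1, Vwf, without HET replicate 12, WT replicate 6 or the library labelled WT replicate 1 or WT replicate 2. Camera called 0 lists with an estimated correlation, 1 in batch 1 alone (fibrillar collagen and fibrosis), 14 in batch 2 alone, 0 in either batch with an estimated correlation, and 4 (without HET replicate 2 or 10) to 13 (without HET replicate 13 or WT replicate 11) with 1 library left out. Within batch 1 alone it called 0 (without HET replicate 3, WT replicate 3 or the library labelled WT replicate 2) to 6 (without HET replicate 2) with 1 library left out. Without the 3 doubted libraries it called 3 in batch 1 alone, the fibrosis list among them. On the slope it called 15 (without the library labelled WT replicate 2) to 23 (without the library labelled HET replicate 6) with 1 library left out. Spearman passed 2 of 22 relations, and neither without the 3 libraries or without the 2 farthest, and r changed sign in 5 of 22 without the 2 farthest libraries. No paired analysis was possible because the labels tie no HET mouse to a WT mouse, and replicate numbers follow the order of deposition. The interaction gave 0 and the batch term 10129 to 13817 genes. The cause was not tested.

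Of 3352 values for the named genes in HET against WT, none past the threshold, 3243 kept their sign, 1 passed (Htr6 without the 3 libraries, 5.67) and 108 reversed, in 26 genes. Of 660 values for the 20 slope genes, 0 reversed and 21 passed. The reversed log2 fold changes lay near 0 except for Igkc and Thy1, and the cause was not tested. With TPM, Gm12895 0.046, Gm12896 0.046, Col1a1 -0.050, Bgn -0.029, Plaur -0.0064, Spp1 -0.034, Thy1 0.012, Lrp2 -0.022, Star -0.048, Mylpf -0.0037, Pvalb -0.021, Bpgm -0.013 and Nefm -0.0016. With FPKM, Bmpr1b -0.00036, Col1a1 -0.064, Bgn -0.045, Plaur -0.018, Spp1 -0.051, Thy1 0.015, Egfl7 -0.0059, Lrp2 -0.039, Tmem72 -0.0023, Cox4i1 -0.0012, Ddost -0.0064, Star -0.058, Pvalb -0.042 and Bpgm -0.027. With voom, Id2 0.026, Pdgfrb 0.0058 and Eng 0.0043. With 6 surrogate variables, Id2 0.083, Cdkn1a -0.0070, Plaur -0.033, Cd74 0.087, Thy1 0.13, Igkc 0.32, Cxcl9 0.028, Pdgfrb 0.067 and Eng 0.049. With DESeq2 size factors, Col1a1 -0.0018. By the DESeq2 Wald test, Col1a1 -0.0016. With no filter, Col1a1 -0.010 and Pvalb -0.0012. With the 1 CPM filter, Col1a1 -0.0011. Without the 3 libraries, Col1a1 -0.045, Bgn -0.0047 and Spp1 -0.013. With no batch term, Cd74 0.019, Eng 0.0049, Lrp2 -0.020, Tmem72 -0.018 and Pvalb -0.012. With 1 library left out in turn, the ranges were Id2 -0.040 to 0.019, Col1a1 -0.059 to 0.044, Bgn -0.024 to 0.042, Spp1 -0.061 to 0.079, Gpnmb -0.56 to 0.076, Cd74 -0.076 to 0.0030, Thy1 -0.16 to 0.028, Pdgfrb -0.063 to 0.00072, Star -0.011 to 0.088 and Pvalb -0.059 to 0.055. A single left-out library moved 32 named genes by over 1.5 times with the sign kept. From 0.4 upward these were Fosb 1.31 to 2.31, Egr3 0.61 to 1.46, S100a8 0.59 to 1.2, Igkc -1.66 to -0.28, Atf3 0.39 to 0.92, S100a9 0.42 to 1.04, Plin1 -0.77 to -0.27, Tbx18 -0.58 to -0.29 and Cd3d -0.62 to -0.33, and the other 23 had log2 fold changes of at most 0.27 in size. Depth limits the low genes, as for Htr6 with 0 to 49 counts a library.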

Other observations

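The counts of other splits for results with 0 genes and with the first principal component, and the choice of the batch 2 genes named here, came after those results were seen, and the other split tests were set before.

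In batch 2 alone, the DESeq2 Wald test called 26 genes, and 7 of them are given here as single genes, with no test of what they share. Higher in HET kidneys were Hyou1 (log2 fold change 0.50, adjusted p = 0.0497), Dnajb11 (0.30, adjusted p = 0.0497) and Selenos (0.29, adjusted p = 0.00312). The bile acid transporter gene Slc10a2 (0.53, adjusted p = 0.0497) and the sterol synthesis gene Cyp51 (0.22, adjusted p = 0.0497) were higher too, and the collagen gene Col5a3 (-0.47, adjusted p = 0.0471) and Mid1 (-0.84, adjusted p = 0.0290) were lower. By edgeR's quasi-likelihood test none of these 7 genes passed in batch 2, and in batch 1 each had the other sign: Hyou1 stood at -0.10, Dnajb11 at -0.05, Selenos at -0.07, Slc10a2 at -0.0072, Cyp51 at -0.02, Col5a3 at 0.09 and Mid1 at 0.12. The median standard error in batch 1 was 0.074 for genes with a mean of at least 1 CPM, so a sign this near 0 says little for several of them. Batch 1 also holds the 3 doubted libraries. These 7 do not stand for all 26 genes. Nbl1, also among the 26, kept its sign by edgeR, at -0.35 in batch 1 and -0.98 in batch 2. The interaction of genotype with batch had an adjusted p of 0.377 for Selenos, 0.520 for Hyou1 and Dnajb11 and 0.557 for Slc10a2, Cyp51, Col5a3 and Mid1.

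Chance can be weighed by other splits of the same libraries, 100 for each result with the real one among them. Where the real count of genes was 0, any split reaches it, so 100 of 100 was fixed beforehand and says nothing of chance; the highest other counts there were 4 for HET against WT over all mice, 61 in batch 1, 42 in the interaction and 3 for the slope on Nbl1. For HET against WT over all mice and genes at an unadjusted p under 0.05, 44 of 100 gave at least the real 755 (highest other 2248), and for lists called by camera 57 of 100 gave at least the real 8 (highest other 18), so chance is not excluded for either. In batch 2, 8 of 100 gave at least the real 1 gene (highest other 30), so chance is not excluded there for the count. A few splits call many more genes than the real one, as in batch 1 and batch 2, which points to some structure of the mice within a batch. What it is was not tested, and the doubted libraries were in these splits.

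For the batch term 1 of 100 splits gave as many as the real 11645 genes (highest other 7), so chance is excluded. For the slope on Nbl1 and genes at an unadjusted p under 0.05, 4 of 100 reassignments of its level gave at least the real 2061 (highest other 2342). That share is close to 0.05, rests on few reassignments and was not corrected for the number of split tests. Chance is therefore not excluded for this gene count. For lists called by camera, 1 of 100 gave as many as the real 20 (highest other 18). Chance is excluded for that list count at the 0.05 level in that model, again without such a correction. Chance is not excluded for either count once the first principal component of the other tested genes is in the model. The genes at an unadjusted p under 0.05 were then 847, with a smallest adjusted p of 0.576, and 43 of 100 reassignments gave at least as many (highest other 2456). The lists called by camera were then 13, and 18 of 100 gave at least as many (highest other 17). The counts therefore do not show a relation to Nbl1 apart from the main axis of variation between the mice. The lists that take part include adipose and urothelium, so a difference in the tissue sampled with each kidney may contribute, and with both scores as covariates the count of genes at an unadjusted p under 0.05 was 1714.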
